A study of soil metagenome with 122 samples.

How the data were processed

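Soil DNA was read as amplicons of a bacterial and a fungal marker from sampling points in 2 avocado orchards in Western Australia, called orchard 1 and orchard 2 here. Per the labels, the soil came from 0 to 10 cm depth, was collected in 2024, and was extracted with a kit made for soil. The points were laid out in 3 designs, a grid, a longitudinal line and a zigzag, and some points served a pair of designs. A point's orchard and designs were read from the code in its title. Titles with the prefix ITS, the internal transcribed spacer used to identify fungi, were taken as fungal libraries. The other titles name no marker and were matched to the bacterial table by identical codes. The columns of the fungal table carry the codes without that prefix, so that a fungal and a bacterial library were paired as one point wherever both tables used the same code.

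The deposited tables hold raw counts of reads per amplicon sequence variant (ASV), a distinct amplicon sequence after error removal, in each library. Per the labels, the authors read the amplicons in pairs of 250 bp on an Illumina MiSeq and built the ASV tables with DADA2 at its default parameters. The submitters' processing notes also name cutadapt and FastQC, without versions. The version of DADA2, the primers, the reference database of the taxon names and the filters applied to the tables are not given in the sources used here. The values show that a filter was applied: no ASV had fewer than 11 reads in total, no nonzero count was below 2, and each ASV had a phylum name. Taxon names are those the authors deposited. No column of per-sample values was left unused. The bacterial table held 61 libraries with 4903 to 32048 reads each, and the fungal one held 60 libraries with 812 to 11373 reads. The fungal library of grid point 9 in orchard 1 was not analysed here. Fungal libraries of 2 points of orchard 1 had fewer than 1000 reads and were left out of all comparisons. Intervals and floors from read counts cover counting error only, because PCR reads are not independent molecules. They were computed on the deposited counts and do not cover reads that a filter removed.

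ASV counts were summed to genus-level taxa. An ASV without a genus name was added to the lowest rank that had a name, written as unclassified with that rank. Relative abundance is a taxon's percent of the reads of a library. Richness and the Shannon index were averaged over 100 random draws of 4903 reads per bacterial and 1149 reads per fungal library (rarefaction). The orchards were compared at the level of ASVs and of genus-level taxa with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (glmQLFit, robust, and glmQLFTest), TMM normalization, taxa found at 10% or more of the points, and Benjamini-Hochberg adjustment at 0.05. Composition was compared by PERMANOVA (vegan 2.7.1) on Bray-Curtis dissimilarity of relative abundances. Richness, Shannon index, phyla with a mean of 1% or more and 13 bacterial and 13 fungal lists of taxa were compared by two-sided permutation tests of the difference in means. Permutation tests used 100000 resamples, so that 1e-05 is the smallest p they can give. Within each orchard, the designs were compared over the points that belong to 1 design only, by PERMANOVA, by a permutation F test of richness and by edgeR over the 3 designs. The ASVs found by the points of each design were set against 10000 random sets of as many points of the same orchard. Bacterial and fungal communities were related by Mantel tests and by correlations of richness.

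The taxa named are those a rule gave. It took the 10 genus-level taxa with the largest fold change in each direction per marker, among those past the test with a mean of at least 0.1% in either orchard, and the 3 taxa with the smallest p in each design comparison, among those past the test. Whether or not they passed, it took the 5 most abundant genus-level taxa per marker, each phylum tested, up to 4 most abundant members of each list, and the 3 most abundant ASVs per marker. The tests, alternatives, lists and this rule were fixed before the data were examined. Where a taxon had no reads in one orchard, its fold is a lower bound computed against a floor of 3 counts over that orchard's total reads. Such a bound holds for the deposited counts. The tables hold no nonzero count below 2, so reads removed before deposit could make it too high. After the data were seen, each bound and fold change was computed again without the point with most of the taxon's reads, and each fold change, phylum, list and design taxon without the point of its highest share, in each orchard in turn or in the leading design. Leaving out the highest point of the orchard with the lower mean widens a difference by construction, so a call gained that way is no support for a difference. The numbers of points in the labels were checked for pairing, and same-numbered points did not pair. Only 1 orchard of each kind was sampled, so p-values measure the spread between points within these orchards.

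The scripts were tested on simulated data. Counts were drawn from a negative binomial model with the real means and library totals, with taxa changed by folds of 4 and 16. Dispersions came from a trend over abundance, fitted without orchard or design, so real differences between orchards count as spread there. Each taxon's own dispersion was not used. The setting thus differs from the data, and the shares below come from single simulations. At the 16-fold change edgeR recovered 74.7% of changed taxa for 943 bacterial ASVs, 87.9% for 359 bacterial genus-level taxa, 84.0% for 151 fungal ASVs and 61.1% for 120 fungal genus-level taxa. At the 4-fold change the shares were 23.4%, 36.2%, 50.0% and 35.0%. Calls of unchanged taxa (the false share) were 49.1%, 16.3%, 46.7% and 30.8% of edgeR's calls, against the 5% aimed at. Changes were simulated without holding library totals fixed, so the shares of unchanged taxa shifted as well. Part of the false share may answer to that shift. Without any simulated change, and so without that shift, edgeR still called 54, 3, 25 and 1 of these taxa. Its adjusted p-values were thus too small in the ASV simulations, and the cause was not tested. In the simulated design comparisons the false share was 33.9% and 31.7% for bacteria and 46.4% and 47.1% for fungi, in orchard 1 and orchard 2. The counts of edgeR still come first, because that test had been fixed in advance. The real data gave a more direct measure. When the orchard labels of the points were shuffled, edgeR's unadjusted p fell under 0.05 for a mean of 4.24% of bacterial ASVs, 4.03% of bacterial genus-level taxa, 20.0% of fungal ASVs and 24.1% of fungal genus-level taxa. When the designs were shuffled, the means were 17.1% and 17.2% for bacteria and 30.0% and 28.9% for fungi. After these results were seen, a permutation test of the ranks of relative abundance was added for each taxon, and its counts stand beside those of edgeR. In the simulated orchard comparisons without any change this rank test made 0 calls. With changes it made no false call among ASVs or fungal genus-level taxa but also recovered 0% of them. In the real data it called 570 of 943 bacterial ASVs, so the simulated recovery does not measure its power there. Among 359 bacterial genus-level taxa it recovered 37.9% at the 16-fold change, with a false share of 31.0%. Because the shares of unchanged taxa also shifted in that simulation, the 31.0% cannot be read as false calls about shares. In the simulated design comparisons it recovered 0% of changed taxa, except 1.59% at the 16-fold change in bacteria of orchard 2, so 0 calls of this test between designs carry no evidence. The permutation test of a difference in means gave a p under 0.05 in 7% of 200 simulations without a difference and 97% with a known one.

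Alternatives were other normalizations, DESeq2 1.42.0, limma 3.58.1 on centred log-ratios with a pseudocount of 0.5, no prevalence filter or one at 25%, other distances, no rarefaction or rarefaction to 1000 reads, the point number as a block, the design as a covariate, and points of a pair of designs left out or entered in both. The library total as a covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9.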

Results

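The series asked how the diversity and composition of soil organisms vary over avocado orchards sampled by different designs. Bacterial libraries came from 30 points of orchard 1 and 31 points of orchard 2, and fungal libraries with enough reads came from 27 and 31 points. Each design had 11 points per orchard, and a point shared by a pair of designs is 1 point here. Bacterial libraries held 19420 ± 5974 reads (SD, n = 30) in orchard 1 and 19872 ± 5971 (SD, n = 31) in orchard 2. The fungal libraries kept held 3988 ± 2432 reads (SD, n = 27) and 4566 ± 1506 reads (SD, n = 31).

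The tables held 5391 bacterial and 543 fungal ASVs. Of the bacterial ASVs, 1725 were found in orchard 1 alone, 2316 in orchard 2 alone and 1350 in both, and those in both held 68.7% of the reads. Of the fungal ASVs, 182, 203 and 158 fell into these classes, and those in both orchards held 81.8% of the reads. Of all ASVs, 2205 bacterial (40.9%) and 147 fungal ones (27.1%) were each found at 1 point only. Haliangium, a myxobacterial genus, and Pseudolabrys, a genus of the Xanthobacteraceae, were among 10 bacterial genus-level taxa found at every point, which together held 26.5% of the reads. No fungal genus-level taxon was found at every point kept.

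The first question was how the bacteria of the orchards differed. Actinobacteriota, a phylum with many filamentous decomposers, made up 24.5% ± 5.34 of reads in orchard 1 (SD, n = 30) and 12.8% ± 6.06 in orchard 2 (SD, n = 31; permutation test, adjusted p = 4.5e-05). Planctomycetota, which divide without the common bacterial division protein, were higher in orchard 2, at 4.85% ± 1.37 and 8.09% ± 2.65 (permutation test, adjusted p = 4.5e-05). Chloroflexi were also higher in orchard 2, at 7.01% ± 2.35 and 9.29% ± 2.93 (permutation test, adjusted p = 0.0048). Myxococcota were 2.17% ± 0.942 and 2.92% ± 1.40 (adjusted p = 0.028) and Gemmatimonadota 1.86% ± 0.879 and 1.37% ± 0.557 (adjusted p = 0.0225). A fall of Actinobacteriota raises the shares of other phyla by arithmetic alone. How much of the rises of Planctomycetota, Chloroflexi and Myxococcota this accounts for was not tested. The call of Myxococcota ended on log2 shares (adjusted p = 0.134) and without its highest point of orchard 2 (adjusted p = 0.0539, and 0.0140 to 0.0416 in the other alternatives), and that of Gemmatimonadota ended for medians (adjusted p = 0.287, and 0.0139 to 0.0371 in the others). Proteobacteria, the most abundant phylum, held 31.2% ± 3.70 and 32.7% ± 3.32 of reads (adjusted p = 0.152), and Acidobacteriota 15.1% ± 3.79 and 16.5% ± 4.51 (adjusted p = 0.257). Bacteroidota (2.34% and 2.65%, adjusted p = 0.322) and Verrucomicrobiota (7.85% and 8.81%, adjusted p = 0.536) did not pass either.

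Among genus-level taxa, Rickettsiella, a genus of intracellular bacteria of arthropods, was found at 28 of 31 points of orchard 2, at 0.172% ± 0.213 of reads, and at 0 of 30 points of orchard 1. On the deposited counts it was at least 345-fold higher in orchard 2, a bound that reads removed before deposit could lower. The lineage NB1-j rose from 0.00227% in orchard 1 to 0.122% in orchard 2 (log2 fold change 5.45, edgeR adjusted p = 8.64e-07), and A0839 from 0.0109% to 0.207% (log2 fold change 4.09). Unclassified members of Opitutaceae, Gimesiaceae, Burkholderiales, Rhizobiaceae, AKYG1722, Amb-16S-1323 and Comamonadaceae were also higher in orchard 2, with log2 fold changes of 3.12 to 3.95. Candidatus Nitrotoga, a nitrite-oxidising genus, was found at 9 points of orchard 1 and none of orchard 2, at least 230-fold higher in orchard 1. Kineococcus was found at 8 points of orchard 1 and none of orchard 2, at least 234-fold higher in orchard 1 and at least 141-fold without grid point 8. Unclassified Bacillales fell from 0.703% ± 1.42 to 0.00834% ± 0.0464 (log2 fold change -6.06, and -5.41 with a mean of 0.453% in orchard 1 without zigzag point 2), Edaphobacter, an acidobacterial genus, from 0.25% to 0.00458% (-5.65) and Rudaea from 0.172% to 0.00479% (-4.88). Unclassified Streptomycetaceae, Rhodanobacteraceae and Microtrichaceae and the genus Ramlibacter were lower in orchard 2 as well, with log2 fold changes of -5.76 to -3.97. The call of Ramlibacter was lost in DESeq2, and that of Opitutaceae with limma on centred log-ratios. Without the point with most of its reads the log2 fold change was -3.26 for Ramlibacter (zigzag point 10 of orchard 1), 3.10 for Opitutaceae (zigzag point 5 of orchard 2) and 3.03 for Burkholderiales (zigzag point 3 of orchard 2), and all 3 kept their calls. Low means rested on few points as well. Unclassified Bacillales, Edaphobacter, Rudaea and unclassified Streptomycetaceae were each found at 1 point of orchard 2. Names above genus in this paragraph cover only ASVs without a genus name. Streptomyces, for example, is counted apart from the Streptomycetaceae here and held 0.471% in orchard 2. Without the highest point of the orchard with the lower mean, the log2 fold change was 6.24 for NB1-j (mean 9.5e-04% in orchard 1), 5.75 for Opitutaceae, 4.60 for Rhizobiaceae, -5.12 for Ramlibacter and -5.32 for Rhodanobacteraceae, and A0839 averaged 0.00702% in orchard 1. Without the highest point of orchard 2, the log2 fold change was 5.27 for NB1-j and 3.27 for Rhizobiaceae. Of the most abundant taxa, unclassified Gaiellales, an actinobacterial order, fell from 8.46% ± 4.19 to 2.83% ± 2.71 (log2 fold change -1.58 ± 0.30 SE, edgeR adjusted p = 1.02e-05) and Pseudolabrys from 5.52% ± 1.92 to 3.39% ± 1.48 (-0.69, edgeR adjusted p = 0.0199, 0.0530 without a prevalence filter, and 0.00129 to 0.0462 in the other alternatives). Unclassified Vicinamibacterales (4.70% and 6.01%), Xanthobacteraceae (4.48% and 4.04%) and Pedosphaeraceae (3.87% and 4.58%) did not pass the test.

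**Figure D1:**
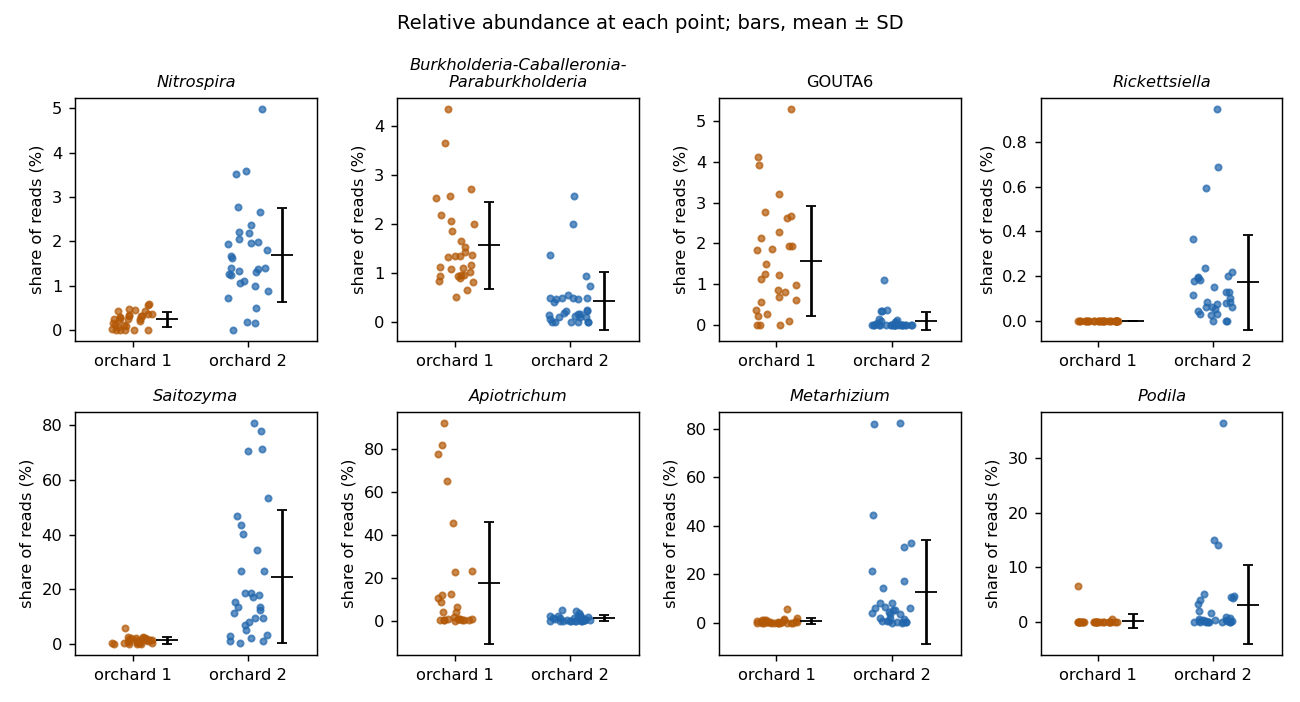
Relative abundance (percent of reads, vertical axis) of 4 bacterial and 4 fungal taxa at each point of orchard 1 and orchard 2. Each dot is a point and the bars give mean ± SD; Nitrospira, for example, averaged 0.238% and 1.69%, and Saitozyma 1.26% and 24.5%.

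Taxa of the nitrogen cycle were examined as fixed lists. Nitrite oxidisers, which turn nitrite into nitrate, rose from 0.358% ± 0.209 of reads in orchard 1 to 1.73% ± 1.06 in orchard 2 (permutation test, adjusted p = 1.2e-04). Nitrospira carried most of this, at 0.238% ± 0.174 and 1.69% ± 1.06 (log2 fold change 2.85, edgeR adjusted p = 6.13e-07). Nitrolancea was found in orchard 2 alone, at 9 points and at least 70.9-fold higher (at least 34.4-fold without grid point 5), while Candidatus Nitrotoga was found in orchard 1 alone. All 3 members tested changed, and 3 passed when adjusted over the list alone. Ammonia-oxidising families, which turn ammonia into nitrite, held 3.77% ± 1.58 and 2.82% ± 1.79 (adjusted p = 0.0636). Of their 7 tested members, 2 were lower in orchard 2, 2 passed when adjusted over the list alone, and 5 did not pass. GOUTA6, a lineage of the Nitrosomonadaceae, fell from 1.57% ± 1.35 to 0.0872% ± 0.216 (log2 fold change -3.97, edgeR adjusted p = 5.35e-05; 0.0535% and -4.98 without longitudinal point 6 of orchard 2), whereas MND1 was at 0.988% and 1.77% (edgeR adjusted p = 0.109, against 0.0205 in the rank test). Rhizobia and other nitrogen-fixing genera held 2.43% ± 0.830 and 1.93% ± 0.893 (adjusted p = 0.0617). Burkholderia-Caballeronia-Paraburkholderia fell from 1.57% to 0.434% (log2 fold change -1.78, edgeR adjusted p = 0.0014) and Bradyrhizobium, which nodulates legumes, rose from 0.460% to 1.14% (1.28, edgeR adjusted p = 0.0243, and 0.0518 and 0.0639 without its highest point of orchard 1 or of orchard 2). The other 3 tested members did not pass, and 2 passed when adjusted over the list alone.

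Of the other bacterial lists, the predatory phyla Bdellovibrionota and Myxococcota were higher in orchard 2, at 2.28% ± 0.994 and 3.13% ± 1.38 (permutation test, adjusted p = 0.0261), with 4 of 19 tested members higher there, 0 passing when adjusted over the list alone, and the call ending on log2 shares (adjusted p = 0.0557, and 0.0115 to 0.0469 in the other alternatives). The part of this rise that follows from the fall of Actinobacteriota by arithmetic was not tested. Cyanobacteria held 0.0056% and 0.0349% (adjusted p = 0.0261), from 3 and 13 points, with a median of 0 in each orchard and 0 of 1 tested members past the test, also when adjusted over the list alone. Verrucomicrobia of bulk soil, such as Candidatus Udaeobacter (1.16% and 0.741%), fell from 1.39% to 0.912% (adjusted p = 0.0437), with 0 of 3 members past the test, also when adjusted over the list alone, and lost the call without the points of a pair of designs (adjusted p = 0.111), without its highest point of orchard 1 (adjusted p = 0.0617) and on log2 shares (adjusted p = 0.176, the highest of its alternatives, with 0.0190 the lowest). Acidobacteriae held 7.13% and 5.08% (adjusted p = 0.226), with 1 tested member of 15 higher in orchard 2 and 3 lower, and 4 passing when adjusted over the list alone. Vicinamibacteria and Blastocatellia held 7.73% and 10.7% (adjusted p = 0.0777), with 1 of 12 higher and 1 lower, namely Vicinamibacter (0.219% and 0.0207%, the latter 0.00925% without zigzag point 9), and 2 passing when adjusted over the list alone. Methane-oxidising families (0.0270% and 0.0178%), endospore-forming genera such as Bacillus (0.164% and 0.135%), filamentous actinobacterial genera such as Streptomyces (0.802% and 0.703%) and gut-associated families (0.00487% and 0.0258%) did not pass, with adjusted p of 0.605, 0.627, 0.605 and 0.152, and 0 members of these lists passed when adjusted over the list alone. Without the highest point, methane-oxidising families averaged 0.00747% in orchard 2, and gut-associated families 0.00193% in orchard 1 and 0.0158% in orchard 2. No ASV was named as an organelle or eukaryote, which a filter before deposit may have fixed.

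Over all taxa tested, edgeR called 119 of 359 bacterial genus-level taxa, 75 higher in orchard 2 and 44 higher in orchard 1, and 518 of 943 ASVs, 292 and 226. Of these calls, 17 genus-level taxa and 215 ASVs were found at fewer than 10 points. The rank permutation test called 167 genus-level taxa, of which 117 were also called by edgeR, and 570 ASVs, of which 481 were. All 20 bacterial taxa named for their fold change passed the rank test. The median log2 fold change of all tested taxa was 0.26 for genus-level taxa and 0.39 for ASVs. Each of these 20 kept its sign relative to that shift, which their choice for large fold changes fixed in advance. The 3 most abundant bacterial ASVs were ASV_3, of the Gaiellales (2.02% and 0.463%), ASV_4, a Pseudolabrys (1.23% and 0.944%) and ASV_5, of the Xanthobacteraceae (0.795% and 1.01%).

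The fungi of the orchards were compared in the same way. Saitozyma, a basidiomycete yeast genus of soil, rose from 1.26% ± 1.25 of reads in orchard 1 (SD, n = 27) to 24.5% ± 24.3 in orchard 2 (SD, n = 31; log2 fold change 5.92 ± 0.78 SE, edgeR adjusted p = 3.31e-09). Apiotrichum, another basidiomycete yeast, fell from 17.6% ± 28.2 to 1.30% ± 1.39 (-3.82, edgeR adjusted p = 9.74e-06). Zigzag point 2 of orchard 1 held 91.9% Apiotrichum, and without it the log2 fold change was -3.57. Metarhizium, a genus known for killing insects, rose from 0.629% ± 1.16 to 12.7% ± 21.5 (6.003, edgeR adjusted p = 5.07e-07). Relative to the median log2 fold change of all tested fungal genus-level taxa, 1.33, these values were 4.58 for Saitozyma, -5.15 for Apiotrichum and 4.67 for Metarhizium. Longitudinal point 4 of orchard 2 held 82.4% Metarhizium. Without that point the genus averaged 10.4% in orchard 2 and its log2 fold change was 5.48. Without zigzag point 9 of orchard 1, Metarhizium averaged 0.434% there and its log2 fold change was 7.23. Fusarium, which includes root and wilt pathogens, held 8.64% ± 9.66 and 6.62% ± 8.30 (edgeR adjusted p = 0.462), and its log2 fold change took either sign in the alternatives. Hyphodiscus held 7.80% ± 17.3 at 12 of 27 points and 1.71% ± 3.52 at 25 of 31 points (log2 fold change -2.01, edgeR adjusted p = 0.0614). Its value was -0.48 without longitudinal point 2 of orchard 1, which held 75.3%, and turned to 1.17 with limma on centred log-ratios, while it passed with total count normalization (adjusted p = 0.0310) and a prevalence filter at 25% (adjusted p = 0.0155), so no direction is claimed. The 3 most abundant fungal ASVs were ASV_1, a Saitozyma (0.996% and 18.1%), ASV_2, a Metarhizium (0.104% and 12.7%) and ASV_4, a Fusarium (8.18% and 5.14%).

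Several fungal taxa were found in one orchard alone. Their bounds are on deposited reads pooled over an orchard. They cover counting error, not the spread between points or reads removed before deposit. Those named next were found at 7 to 10 of 31 points of orchard 2 or at 6 to 13 of 27 points of orchard 1. Trichobolus, found at 9 points of orchard 2, was at least 439-fold higher there, Pseudophialocephala at least 366-fold, Veronaea at least 169-fold, unclassified Bionectriaceae at least 142-fold, Arthrographis at least 94.8-fold, Oliveonia at least 69.7-fold and the yeast Tausonia at least 50.2-fold. Leucocoprinus, a genus of litter-decomposing mushrooms found at 8 points of orchard 1, was at least 742-fold higher there, with 1412 of its 1694 reads at zigzag point 6, Dactylonectria at least 578-fold, Rhizophydiaceae at least 377-fold, Keratinophyton at least 342-fold, unclassified Chaetosphaeriaceae at least 194-fold and Amorocoelophoma at least 98.2-fold. Without the point with most of its reads, Trichobolus was at least 213-fold higher in orchard 2, Pseudophialocephala at least 148-fold, Veronaea at least 80.0-fold, unclassified Bionectriaceae at least 85.3-fold, Oliveonia at least 46.3-fold and Tausonia at least 32.8-fold. In orchard 1 Leucocoprinus was then at least 138-fold higher, Rhizophydiaceae at least 250-fold, Keratinophyton at least 143-fold and unclassified Chaetosphaeriaceae at least 94.97-fold. The bounds of Arthrographis, Dactylonectria and Amorocoelophoma moved by less than 1.5 times. Cephaliophora, Ectophoma and Lasiobolidium were also higher in orchard 2, with Ectophoma at 1 point of orchard 1 and 21 of orchard 2. Cephaliophora had a log2 fold change of 6.68 and of 5.21 without grid point 4, and Lasiobolidium of 6.25 and of 5.17 without grid point 1. Without the highest point of orchard 1 the values were 7.69 and 7.73, and 7.03 for Ectophoma. For Ectophoma the value was 6.01 without longitudinal point 8 of orchard 2. Coniochaeta fell from 4.21% ± 5.45 to 0.0899% ± 0.382 (log2 fold change -5.94), the yeast Solicoccozyma from 0.356% to 0.00761% (-4.80) and Chloridium from 4.42% ± 14.6 to 0.163% ± 0.417 (-4.37). Chloridium held 76.0% of the reads at longitudinal point 6 of orchard 1. Without that point its mean there was 1.67% ± 2.996 (SD, n = 26), its log2 fold change was -1.92 and its call was lost (edgeR adjusted p = 0.0710), as it was with the design as a covariate. Cystoderma, at 7 points of orchard 1 and 1 of orchard 2, lost its call in DESeq2, and its log2 fold change of -5.49 was -3.09 without longitudinal point 2 of orchard 1 and -6.54 without its point of orchard 2. Without the highest point of orchard 2, Coniochaeta averaged 0.0261% there (log2 fold change -7.35), Solicoccozyma 0.00442% (-5.76) and Chloridium 0.0993%. Without grid point 4 of orchard 1, Coniochaeta averaged 3.55% there and its log2 fold change was -5.65.

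No fungal phylum passed the permutation test. Ascomycota held 73.8% ± 27.3 and 67.4% ± 24.99 of reads (adjusted p = 0.418), Basidiomycota 22.7% ± 27.6 and 28.2% ± 23.9 (adjusted p = 0.418) and Mortierellomycota 0.731% ± 1.62 and 3.37% ± 7.25 (adjusted p = 0.107). No fungal list passed as a sum either. On log2 shares the phylum Mortierellomycota passed (adjusted p = 0.0135), as did the lists of soil yeasts (adjusted p = 0.0462) and Mortierellomycota (adjusted p = 0.0450). Members changed in opposite directions in soil yeasts, genera with plant pathogens and Mortierellomycota. Soil yeasts held 19.3% ± 28.5 and 26.4% ± 23.9 (adjusted p = 0.433), while 5 of their 7 tested members were higher in orchard 2 and 2 were lower, and 7 passed when adjusted over the list alone. One of the 5, Papiliotrema (0.0312% and 0.145%), did not pass the rank test (adjusted p = 0.790) and lost its edgeR call without the point with most of its reads (adjusted p = 0.0719). Genera with plant pathogens held 9.75% and 7.40% (adjusted p = 0.436). Dactylonectria, known from black-foot root disease, was found in orchard 1 alone, and Neofusicoccum, a genus of branch canker and fruit rot fungi, rose from 0.000651% at 1 point to 0.282% at 16 points (edgeR adjusted p = 1.43e-07), and to 0.166% without zigzag point 2. Plectosphaerella was at 0.142% (0.0693% without zigzag point 9) and 0.444% (edgeR adjusted p = 0.0172, 0.140 with total count normalization, and 0.00342 to 0.0626 in the other alternatives), and 3 of the 5 tested genera passed when adjusted over the list alone. Mycoparasitic and insect-pathogenic genera held 5.30% and 13.96% (adjusted p = 0.129), with 1 of 2 members past the test, 1 when adjusted over the list alone. Trichoderma, a mycoparasite, was at 4.67% ± 4.72 and 1.22% ± 1.89 (edgeR adjusted p = 0.637, against 0.0213 with total count normalization, 0.0562 to 0.969 in the other alternatives and 0.0111 in the rank test).

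Mortierellomycota, fast-growing soil saprotrophs, included Podila, which rose from 0.271% at 3 points to 3.23% at 26 points (log2 fold change 4.49, edgeR adjusted p = 3.8e-04, and 3.65 with a mean of 2.12% in orchard 2 without its highest point there). Without zigzag point 5 of orchard 1, Podila averaged 0.0273% there and its log2 fold change was 7.85. Mortierella held 0.358% and 0.147% (edgeR adjusted p = 0.987), and 0.193% in orchard 1 without grid point 2. Its log2 fold change also took either sign in the alternatives, and 2 of 3 tested members passed when adjusted over the list alone. As a list they had an adjusted p of 0.129. Of the moulds Penicillium, Aspergillus, Talaromyces and Cladosporium (3.61% and 7.54%, adjusted p = 0.129), 1 passed when adjusted over the list alone. Aspergillus rose from 0.230% to 2.75% (log2 fold change 5.16, edgeR adjusted p = 2.27e-05). Without grid point 10 of orchard 1 it rose from 0.129%, with a log2 fold change of 5.81. Without the point of orchard 2 shared by grid and zigzag, Aspergillus averaged 2.37% there and its log2 fold change was 4.86. Of the nematode-trapping genera only Arthrobotrys was found, at 1 point and 5 points (list adjusted p = 0.158; 1 passed when adjusted over the list alone, with a rank test adjusted p of 0.153). Chytridiomycota and Rozellomycota held 2.79% and 1.02% (adjusted p = 0.168), with 2 of 7 tested members lower in orchard 2 and 2 passing when adjusted over the list alone, and 1.63% in orchard 1 without grid point 4. Saprotrophic Agaricomycetes held 1.06% and 0.142% (adjusted p = 0.158) and cellulolytic Sordariomycetes 0.0969% and 0.0366% (adjusted p = 0.528), with 0 members past the test, also when adjusted over the list alone. In orchard 1 the Agaricomycetes averaged 0.331% without zigzag point 5 and the Sordariomycetes 0.0365% without zigzag point 7. In orchard 2 the Agaricomycetes averaged 0.0678% without longitudinal point 2, and the Sordariomycetes were found at 1 point. Arbuscular mycorrhizal fungi, root symbionts of most crops, were represented by 1 ASV, a Dominikia, at 1 point of orchard 2 (0.0119% on average, adjusted p = 1). No ASV belonged to the ectomycorrhizal genera, to Mucoromycota or to another kingdom. The tables were filtered before deposit, so this absence cannot be read as absence from the soil.

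Over all fungal taxa tested, edgeR called 75 of 120 genus-level taxa, 48 higher in orchard 2 and 27 higher in orchard 1, and 110 of 151 ASVs, 65 and 45. Of these calls, 30 genus-level taxa and 55 ASVs were found at fewer than 10 points. With total count normalization the split of genus-level taxa was 38 and 35. The median log2 fold change of all tested genus-level taxa was 1.33, against 0.26 with total count normalization, and 0.87 against 0.12 for ASVs. The 20 fungal taxa named for their fold change passed the rank test. They kept their sign relative to this shift, which their choice for large fold changes fixed in advance. On shuffled labels edgeR gave an unadjusted p under 0.05 for 24.1% of fungal genus-level taxa. The rank permutation test called 71 genus-level taxa, 36 higher in orchard 2 and 35 higher in orchard 1, of which 58 were shared with edgeR, and 98 ASVs.

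Whole communities differed between the orchards. Bray-Curtis dissimilarity of bacteria averaged 0.706 ± 0.131 (SD) between points of orchard 1, 0.743 ± 0.101 within orchard 2 and 0.846 ± 0.0662 across orchards. For fungi the averages were 0.774, 0.752 and 0.894. The orchard accounted for 16.05% of the variation in bacteria and 16.1% in fungi (permutation test on distances, p = 1e-05 for both, the smallest they can give). The spread of points around their orchard's centre did not differ for bacteria (permutation p = 0.248) or fungi (permutation p = 0.598).

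**Figure D2:**
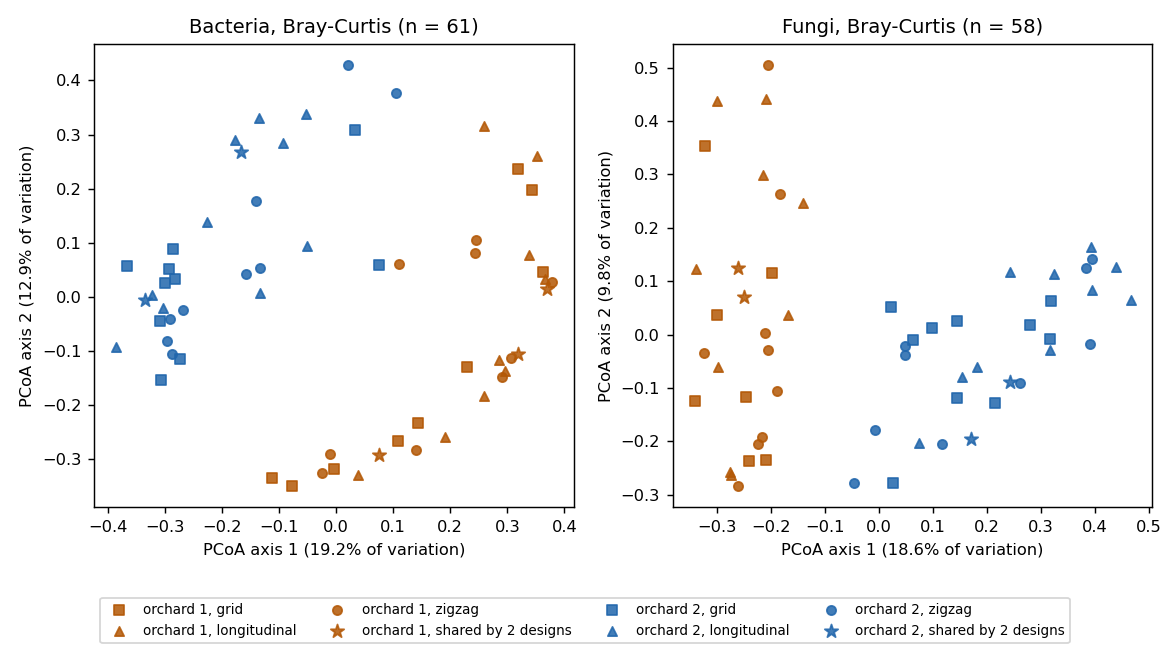
Principal coordinates of Bray-Curtis dissimilarity for bacteria and fungi, with the share of variation on each axis. Each symbol is a point, coloured by orchard and shaped by design; the orchard accounted for 16.05% of the bacterial and 16.1% of the fungal variation.

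Rarefied bacterial richness was 357 ± 97.8 ASVs (SD, n = 30) in orchard 1 and 395 ± 107 (SD, n = 31) in orchard 2, a difference within the spread between points (permutation p = 0.157). This measure followed the library total within each orchard, with Pearson r = 0.860 (Spearman rho 0.769) in orchard 1 and 0.919 (Spearman rho 0.884) in orchard 2, and r = 0.766 and 0.908 without the 2 farthest points. The common slope was 168 ASVs per doubling of the total (permutation p = 1e-05, the smallest they can give). After adjustment for the library total, chosen after the data were seen, orchard 2 was higher by 32.7 ASVs (permutation p = 0.00743). The Shannon index of bacteria was 5.41 ± 0.339 and 5.47 ± 0.383 (permutation p = 0.5255). Fungal richness was 50.2 ± 20.3 and 50.6 ± 15.3 ASVs (permutation p = 0.932), and the fungal Shannon index 2.67 ± 0.856 and 2.63 ± 0.733 (permutation p = 0.827).

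**Figure D3:**
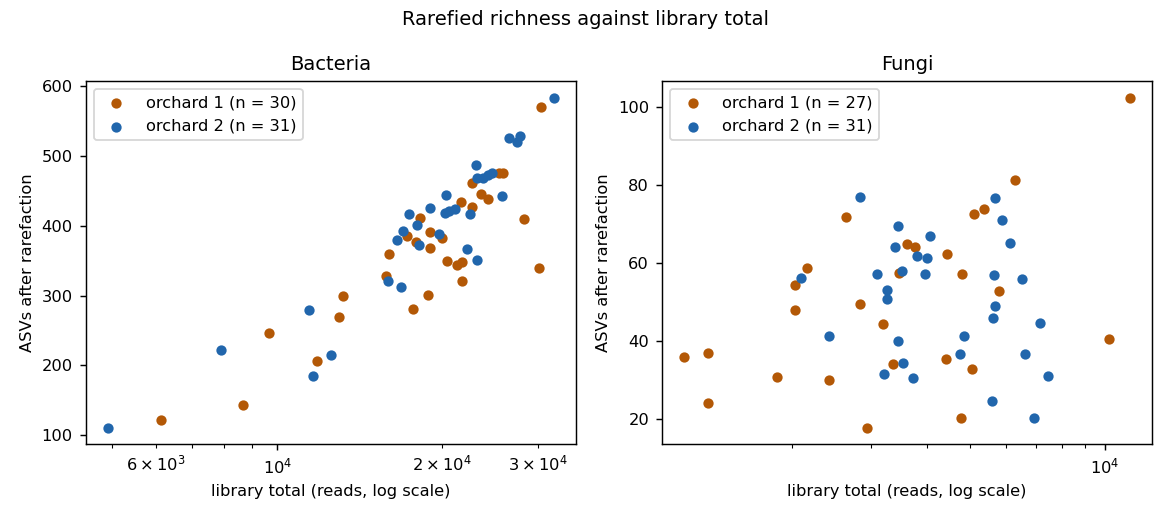
ASVs after rarefaction (vertical axis) against the library total in reads (horizontal axis, log scale) for bacteria and fungi, each dot a point coloured by orchard. Bacterial richness rose with the library total, with Pearson r = 0.860 in orchard 1 and 0.919 in orchard 2; for fungi r was 0.484 and -0.218.

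The second question was whether the sampling design changed the picture of an orchard. The designs of orchard 1 accounted for 10.3% of bacterial variation (permutation test on distances, p = 0.0929) and 10.7% of fungal variation (permutation p = 0.112), where 7.69% and 8.33% are expected by chance. In orchard 2 the shares were 8.12% (permutation p = 0.199) and 9.95% (permutation p = 0.0682), with 7.14% expected for both. Bacterial variation in orchard 1 passed 0.05 on Jaccard (permutation p = 0.0334) and Aitchison distances (permutation p = 0.0429), and fungal variation in orchard 2 passed on Aitchison distance (permutation p = 0.0451). The interaction of design and orchard did not pass for bacteria (permutation p = 0.252) or fungi (permutation p = 0.0619).

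Bacterial richness in orchard 1 was 365 ± 89.4 ASVs on the grid, 403 ± 87.8 on the longitudinal line and 302 ± 109 on the zigzag (n = 9 each, permutation p = 0.0999, and 0.906 after adjustment for the library total). In orchard 2 it was 413 ± 42.8 (n = 10), 393 ± 108 (n = 10) and 371 ± 163 (n = 9; permutation p = 0.726). Fungal richness did not differ between designs in orchard 1 (permutation p = 0.7096) or orchard 2 (permutation p = 0.286).

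The design comparisons of taxa gave no call in the rank permutation test, with 22 of 348 bacterial and 11 of 111 fungal genus-level taxa at an unadjusted p under 0.05 in orchard 1, and 16 of 377 and 13 of 116 in orchard 2. In simulated design comparisons this test recovered 0% of taxa changed by 4-fold, and of those changed by 16-fold 0% in 3 comparisons and 1.59% in bacteria of orchard 2, so its lack of calls is no evidence that designs were alike. In edgeR 10 bacterial and 33 fungal taxa of orchard 1 and 14 and 26 of orchard 2 passed, and in DESeq2 0, 1, 0 and 0. The taxa edgeR placed first were found at few points. Unclassified Chaetosphaeriaceae averaged 2.38% ± 3.17 on the grid of orchard 1, from 5 of 7 points, unclassified Rozellomycota 4.88% ± 12.1 there, from 3 points with a highest share of 32.2%, and Leucoagaricus 2.31% ± 6.65 on the zigzag, from 2 points. In orchard 2, unclassified Latoruaceae averaged 3.50% ± 10.4 on the grid from 2 of 10 points, Paraphaeosphaeria 0.386% there from 3 points, and Coprinopsis 0.284% on the longitudinal line from 4 points. The bacteria were MVP-88, Subgroup 22 and Planctomicrobium in orchard 1 and Vicinamibacter, B12-WMSP1 and Methylovirgula in orchard 2, found at 3 to 4 points of their leading design. Without the highest point of that design the means were 1.42% for Chaetosphaeriaceae, 0.322% for Rozellomycota, 0.0984% for Leucoagaricus, 0.208% for Latoruaceae, 0.222% for Paraphaeosphaeria and 0.0516% for Coprinopsis. Rozellomycota (edgeR adjusted p = 0.530), Leucoagaricus (edgeR adjusted p = 0.0849) and B12-WMSP1 (edgeR adjusted p = 0.0662) then lost their calls, Chaetosphaeriaceae and Coprinopsis kept theirs, and the other 7 were found at too few points to be tested.

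The share of the orchard's pooled ASVs that a design found was set against random sets of points, and none passed after adjustment. For bacteria of orchard 1 the grid found 59.6%, the longitudinal line 60.7% and the zigzag 53.5% of 3042 ASVs, and in orchard 2 the shares were 57.8%, 56.0% and 60.8% of 3626 ASVs. For fungi they were 62.6%, 58.6% and 66.0% of 326 ASVs in orchard 1 and 64.4%, 57.6% and 66.7% of 354 ASVs in orchard 2. The fungal shares of orchard 1 rest on 9 points of the grid and 10 of each other design. Random sets of 9 and 10 points averaged 62.2% and 65.6% there. The lowest p among these comparisons with random sets was that of the bacterial zigzag of orchard 1 (permutation p = 0.0380, adjusted p = 0.456). Zigzag points 3, 2 and 4 had the lowest bacterial library totals of that orchard (6122, 8675 and 9654 reads). Rarefied bacterial richness followed the library total, so this comparison does not separate design from depth.

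**Figure D4:**
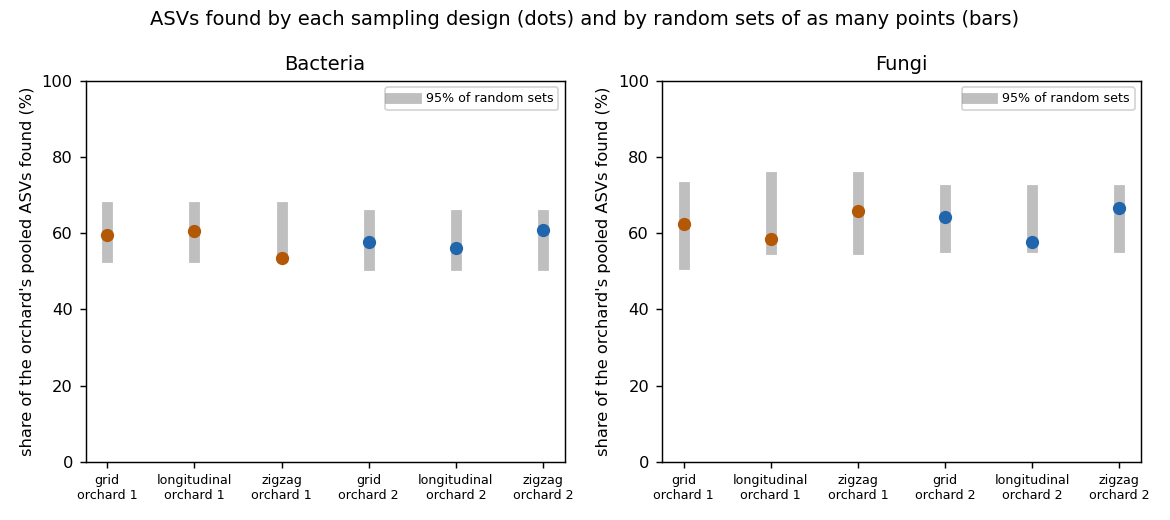
Share of the orchard's pooled ASVs found by the points of each design (dots, vertical axis from 0 to 100%) and the range of 95% of random sets of as many points (grey bars), for bacteria and fungi in each orchard. The bacterial zigzag of orchard 1 was the lowest, at 53.5%.

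Finally, bacterial and fungal communities were related over points. Points that differed in bacteria also differed in fungi, with a Mantel rho of 0.486 over 27 points of orchard 1 (permutation p = 2e-05, adjusted p = 4e-05) and 0.297 over 31 points of orchard 2 (permutation p = 0.0011, adjusted p = 0.0011). Bacterial and fungal richness were correlated in orchard 1 (Pearson r = 0.536, permutation p = 0.00418, adjusted p = 0.0167; Spearman rho = 0.477, permutation p = 0.0128), and r was 0.481 without the 2 farthest points. In orchard 2 Pearson r was 0.297 (permutation p = 0.104) and Spearman rho 0.379 (permutation p = 0.0368, adjusted p = 0.0491), in a family of 4 correlations, and r was 0.388 without the 2 farthest points. After adjustment for library totals r was 0.471 (permutation p = 0.0128) in orchard 1 and 0.452 (permutation p = 0.0105) in orchard 2. Whether the relation differed between orchards was not tested.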

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

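The counts over shuffled splits, the test of the slope of richness and the test of the median count per ASV were chosen after their results or the pattern had been seen. No group of 4 to 10 points had a point far enough from the others to stand apart in richness, Shannon index or distance to the centre, among 36 sets of points and measures tested, where chance alone would single out about 1 in 20.

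Random splits of the points were set against the calls of edgeR, in 100 splits that include the real one. For the orchards the real split alone gave as many calls (1 of 100 splits each). It gave 518 bacterial ASVs against at most 13 in the others, 119 bacterial genus-level taxa against 6, 110 fungal ASVs against 26 and 75 fungal genus-level taxa against 31. A chance division of the points can thus be excluded for the size of these counts, but not for single calls. The other splits gave medians of 2, 0, 9 and 11 calls. With 1 orchard on each side, the splits show only that points differed by place. For the designs, 29 of 100 splits of bacteria in orchard 1 gave 10 calls or more, with a highest of 92. Structure among the points other than the design may lie behind that split, but edgeR's p was also too often small on shuffled designs (under 0.05 for 17.1% of these taxa on average), and the cause of the 92 was not tested. In bacteria of orchard 2, 9 of 100 gave 14 or more, with a highest of 34, and in fungi of orchard 2, 27 of 100 gave 26 or more, with a highest of 38, so chance cannot be excluded for these. For fungi of orchard 1 only the real split reached 33, with a highest of 31 among the others.

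Rarefied bacterial richness rose with the library total, by 168 ASVs per doubling, and a chance relation is excluded by the permutation p of 1e-05, the smallest they can give. Dropping ASVs with 1 read from each library, imitated by thinning 33 deep libraries to 50%, accounted for 0.0120 of that slope, and dropping counts under 7 reads for 0.362 of it, so neither accounts for the whole. Only libraries with at least 4 times the rarefaction depth were thinned, so these shares may not hold for shallow ones. Rarefaction itself removed few ASVs: in the deepest library, zigzag point 7 of orchard 2, it lowered the count from 622 to 584. What stays open is a gradual loss, from shallow libraries before deposit, of ASVs with more reads than these limits. The median nonzero count per ASV had a log-log slope of 0.0689 ± 0.0389 (SE) on the library total. This follows from the rise of richness with the total, so that the test leaves such a loss open. Points that hold more kinds of bacteria and also yield more reads were not tested and may give the same slope.

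Apiotrichum was lower and Saitozyma higher in orchard 2. A rise of one yeast lowers the share of the other by arithmetic alone. However, Apiotrichum fell from 17.8% to 1.90% of the reads that are not Saitozyma (permutation p = 1.8e-04), and Saitozyma rose from 2.37% to 24.8% of the reads that are not Apiotrichum (permutation p = 1e-05), which argues against this as the cause. A few points with very high shares do not account for the directions either, since the medians moved from 4.04% to 0.861% and from 1.11% to 15.3% (larger permutation p = 1.5e-04). The size of the fall in the mean of Apiotrichum does rest in part on such points. Its mean in orchard 1 was 17.6%, far above the median, and zigzag point 2 there held 91.9%. A difference between the orchards' soils may lie behind it, as a hypothesis not tested here, and differences in handling between orchards cannot be excluded since no batch was given.

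Rickettsiella was found at 28 of 31 points of orchard 2 and none of orchard 1. Reagent contamination predicts a share that falls as the library total rises. In orchard 2 the Spearman rho was 0.181 (permutation p = 0.329). By the rule written beforehand a rho at or above 0 counted against contamination. After the result was seen, the test was read as leaving contamination open, since the value lies within its spread of 0. The share of Rickettsiella ran from 0.0258% to 0.949% where found. An arthropod host living in orchard 2 is another candidate explanation, which was not tested.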

How the results depend on the processing

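The rank permutation test, each adjustment for library totals and each value without a leading point were chosen after the data were seen. The difference of whole communities between orchards kept its side of the threshold under every distance, block and covariate run. For values named in this part the cause of a change was not tested, except that a prevalence filter changes how many taxa are tested. Without a prevalence filter edgeR called 4373 bacterial ASVs, 320 bacterial genus-level taxa, 452 fungal ASVs and 156 fungal genus-level taxa between orchards. The bacterial table held 5391 ASVs, of which 2205 were found at 1 point only. The 4373 calls thus include ASVs found at 1 point, which cannot show a difference between orchards. With a filter at 25% of points edgeR called 149, 76, 38 and 36. DESeq2 called 70 fungal ASVs and 49 fungal genus-level taxa. On log2 shares 2 bacterial lists, 1 fungal phylum and 2 fungal lists passed. Keeping only reads with a named phylum, or all bacterial libraries, moved nothing and so tests nothing.

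Between designs, the calls without a prevalence filter were 144 and 183 for bacteria and 80 and 81 for fungi, in orchard 1 and orchard 2. DESeq2 gave 0 and 0 for bacteria and 1 and 0 for fungi, and the rank permutation test, which recovered next to nothing in simulated designs, 0 in all 4. With shared points entered in both designs bacteria gave 0 and 0, and with the library total as a covariate 24 and 37. The designs' share of variation passed the threshold for bacteria of orchard 1 on Jaccard (0.0981) and Aitchison distance (0.0988), and for fungi of orchard 2 on Aitchison distance (0.0869).

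Point numbers do not pair the points: profiles with the same number in the other orchard had a mean correlation of 0.0517 in bacteria (6 of 24 pairs over 0.1) and 0.0431 in fungi (7 of 23), and across designs 0.0585 (20 of 49) and 0.0801 (17 of 45). With the number as a replicate block, the design calls were 0 and 0 for bacteria and 4 and 1 for fungi, and the designs' share of variation passed for bacteria of orchard 1 (0.0903, permutation p = 0.00471) and fungi of orchard 2 (0.110, permutation p = 0.0417). MND1 gained a call with this block (log2 fold change 1.92, adjusted p = 0.0314). With this block the log2 fold change turned its sign for IS-44 (0.72), Mesorhizobium (0.14), Paenibacillus (0.0172), Subgroup 2 (-0.62), Chthoniobacter (0.33), Hyphodiscus (3.94), Trichoderma (0.0597), Penicillium (-0.57), Talaromyces (-0.59), unclassified Rozellomycota (3.99) and Terramyces (-2.94).

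Other log2 fold changes that turned belonged to taxa that had not passed the test. With limma on centred log-ratios they were IS-44 (0.34), Subgroup 2 (-0.66), Fusarium (-0.27), Hyphodiscus (1.17), Mortierella (-0.34), Penicillium (-0.76), Talaromyces (-0.29), unclassified Rozellomycota (2.02) and Terramyces (-1.81). In DESeq2 they were Fusarium (-0.00459), Mortierella (-0.42), Talaromyces (-0.00268), unclassified Rozellomycota (3.19) and Terramyces (-2.27). With total count normalization Fusarium (-0.38), Mortierella (-1.27) and Terramyces (-0.0925) turned, and with TMMwsp Mortierella (-0.28). Without a prevalence filter Fusarium (-0.0671) and Mortierella (-0.48) turned, and at 25% Fusarium (-0.0245) and Mortierella (-0.78). With the design as a covariate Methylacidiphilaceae (0.11), Mortierella (-0.40) and unclassified Rozellomycota (2.82) turned, and with the library total Mortierella (-0.0132) and unclassified Rozellomycota (2.53). Without shared points Mortierella (-0.51) turned, and with all libraries kept Branch03 (0.0480). Without the point with most of a taxon's reads or the highest point of either orchard, the values ran from -0.0516 to 0.43 for Subgroup 2, -2.41 to 0.22 for Branch03, -0.66 to 0.00570 for Cladosporium, -3.59 to 0.54 for Mycena, -0.49 to 0.16 for Mortierella, -1.94 to 1.16 for Terramyces and -0.95 to 3.99 for unclassified Rozellomycota, and the difference in shares from -0.0540 to 0.00889 percentage points for endospore-forming genera and -0.0969 to 7.66e-05 for cellulolytic Sordariomycetes. Some of these passed the test in the turned direction: unclassified Rozellomycota in DESeq2 (adjusted p = 0.00741), in limma (0.0142), with the block (0.00951) and without grid point 4 of orchard 1, which held 370 of the 466 reads it had there (9.29e-04), Terramyces in limma (0.0242) and with the block (0.0451), and Hyphodiscus with the block (0.0252), so no direction is claimed for them. Over all alternatives of single taxa, 1193 values kept direction and side of the threshold, 24 lost a call, 19 gained one and 52 turned. The 19 include any call gained by leaving out the highest point of the orchard with the lower mean.

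Adjusted for library totals, the orchard difference in bacterial richness was 32.7 ASVs and passed, in fungal richness -1.74 ASVs and in fungal Shannon index 0.0307, and the richness correlation of orchard 2 was 0.452 and passed. The difference in fungal spread turned on Jaccard (0.00193) and Aitchison distance (1.01), and the median share of Verrucomicrobiota differed by -0.834 percentage points. Against random sets, the share of taxa found turned its sign for the bacterial longitudinal line of orchard 1 at genus level (-0.923 percentage points) and with 2 reads or more (-0.532), the bacterial grid of orchard 2 (2.54) and the fungal zigzag of orchard 2 (-0.643) at genus level, and the fungal grids without rarefaction (-1.44 and -1.24). Depth limits the fungi in that libraries under 1000 reads were left out and richness was set at 1149 reads.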

Other observations

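Both tests of this part were written down before their results were seen. If neighbouring numbers of a design were neighbours in the field, points with close numbers may share more taxa. The mean Mantel rho of the number gap and Bray-Curtis dissimilarity over 6 sets of points was 0.135 for bacteria (one-sided permutation p = 0.0302, 10000 resamples) and -0.0161 for fungi (p = 0.580). For bacteria the rho was 0.379, 0.495 and 0.321 on the grid, longitudinal line and zigzag of orchard 1 and -0.208, -0.00319 and -0.172 in orchard 2. By the rule written beforehand a mean rho at or below 0 counted against shared taxa of neighbours. After the result was seen, the fungal test was read as leaving the question open, since its value lies within its spread of 0. The bacterial value rests on orchard 1, it was not adjusted for testing 2 markers, and the order of the points in the field was not given in the sources used here.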
